A study of Rattus norvegicus with 28 samples.

How the data were processed

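Total RNA of purified rat retinal ganglion cells (postnatal day 4) was measured on 28 Affymetrix Rat Genome 230 2.0 arrays, each hybridised with biotin-labelled RNA of a single sample. Groups were taken from the sample titles: 5 arrays with KLF7, 6 with KLF9, 6 with KLF11, 6 with KLF16 and 5 with FLAG-tagged mCherry. Per the labels' protocols, the KLF open reading frames and mCherry were cloned into a lentiviral expression vector. The labels do not say whether samples of a group came from separate cultures or litters, so p-values measure the spread between these samples, which may be technical.

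The authors deposited 4 tables, each setting the arrays of 1 KLF beside the same 5 mCherry arrays. Per the file headers, each table holds intensity values on a linear scale, one per probe set and array, already summarised from single probes. The same tables hold deposited log2 values that equal log2 of the intensity minus the probe set's median within the table. Per the file headers, the deposited p-value and its corrected form come from an unpaired t-test with asymptotic p and Benjamini-Hochberg adjustment, and a linear fold and its log2 accompany them. Per the file headers, the entity list of the KLF7 and KLF11 tables was filtered between the 1.0 and 100.0 percentile, and that of the KLF9 and KLF16 tables was not. The probe summarisation method and the genome build behind the deposited alignments are not given in the sources used here. The series table mixes scales, with linear intensity for KLF7 arrays and median-centred log2 values for the others, and matched the 4 tables at 100.0% of probe sets, so it added no other values and was not used further.

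The mCherry arrays do not have the same values in the 4 tables, which were therefore normalised separately. Per gene, the difference between 2 tables varied over the mCherry arrays with a median SD of 0.0438 to 0.0517 log2 units. The median SD between mCherry arrays was 0.169 to 0.182. The first SD leaves out a constant shift between tables. That shift averaged up to 0.115 log2 units over all genes, and its usual size in a single gene was not measured. It can be large: Klf16 averaged 7.24, 2.87, 6.26 and 5.40 log2 units on mCherry arrays in the KLF7, KLF9, KLF11 and KLF16 tables. Levels are therefore compared only within a table. The design fixed before the data were examined put all 28 arrays in 1 fit. That could not hold for values normalised in 4 parts, so each comparison with mCherry was fitted within its own table. No table holds more than 1 KLF, so comparisons between KLFs used each array's log2 ratio to the mCherry mean of its own table, joined in 1 fit over all arrays. The spread between tables is not part of the error of those comparisons.

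All tests used log2 of the deposited intensity with no further scaling. Of 31099 probe sets, 57 were controls and left out. The deposited annotation gave 1 gene symbol for 20826 probe sets, several for 436 and none for 9780, and 20764 of those with 1 symbol were matched to a current symbol by Entrez identifier. Each of 14217 genes was represented by its probe set with the highest mean, and genes with several probe sets can differ between them. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes on group means, no replicate block), with Benjamini-Hochberg adjustment over the genes and a threshold of 0.05. Each change is given in log2 units as KLF minus mCherry, with the standard error (SE) of the fit. The words rose, fell and changed are used only past that threshold. Single genes of special interest also had a two-sided exact permutation test of the array values. The arrays give no counts, so their number alone limits the precision. A measure of signal over background was not used here, so the size of a change is uncertain where 1 of its levels lies well under the array median.

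Fixed before the data were examined were 28 gene lists, covering neuronal functions, signalling responses, metabolism, growth control and markers of other retinal cell types. They were tested with camera (preset correlation of 0.01, adjusted over the lists), with camera at an estimated correlation, and with fry, which asks whether a list moves on balance one way without setting it against other genes. Member counts are given over all genes tested and adjusted over the list alone, and totals over lists include all 28. The result of 1 list is not reported here. Gene Ontology terms and a list of branched-chain amino acid enzymes were added after the data were seen.

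The genes named were chosen by a rule fixed before the data were examined. It takes the transduced KLF, the 8 largest rises and 8 largest falls past the threshold with every KLF array on that side of the mCherry mean, up to 4 members past the threshold of each list by absolute change, and Dusp14. For comparisons between KLFs it takes the 6 largest rises and 6 largest falls. For genes changed alike by all 4 KLFs it takes 6 per direction with the largest smallest change, and for opposite changes 6 per pair of KLFs by the product of the changes. Fewer are named, from the top of each ranking. Some genes whose call rested on a single array gave way to the next in the ranking, a choice made after their values were seen.

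Replicate numbers from the labels are shared by the groups, apart from number 3, which KLF7 and mCherry lack. Deviations from the group means were correlated between arrays of the same number in every pair, from 0.297 to 0.710 for KLF7, 0.131 to 0.661 for KLF9, 0.100 to 0.502 for KLF11 and 0.274 to 0.674 for KLF16. Arrays of different numbers averaged -0.0915, -0.0710, -0.0687 and -0.0861. The numbers therefore pair the samples, and in the comparisons with mCherry values with the number as a block are given where they change a camera call or the call of a named gene or move a count by over 1.5-fold. List tests between KLFs were not run with the block.

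Other settings tried were the replicate block, each array left out in turn, an equal-variance t-test on the same values, trended and robust variance, array weights, quantile normalisation and median centring on top of the deposited values, the dimmest 40% of genes left out, all probe sets, a 1.5-fold minimum and an adjusted p under 0.01. Joining all arrays in 1 fit and leaving out the arrays numbered 1 were added after the data were seen. The shared mCherry arrays were handled with 100 simulations of unchanged groups and with 20 splits of those arrays. Fits, list tests and counts were tested on simulated data with 200 changed genes, 50 at each of 4 sizes. At a true change of 2-fold the test found 85.9% of those 50 for KLF7, 88.3% for KLF9, 89.0% for KLF11 and 86.7% for KLF16, and at 1.2-fold 28.6%, 32.8%, 34.6% and 30.4%. In 2, 4, 5 and 3 of 20 simulations it also called over 100 unchanged genes, up to 699, 2850, 2558 and 1716, and the highest for KLF11 lies above its count of 461 in the data. The simulated groups were drawn independently, which leaves out the correlation between arrays of the same number. With a list planted at 0.5 log2 units, camera with the preset correlation also called a median of 3, 3, 4.5 and 5 of the 27 unchanged lists per simulation, about as many lists as it called in the data, and with an estimated correlation it called a median of 0. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for the other steps. No gene that the deposited annotation leaves without a symbol was named.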

Results

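Krüppel-like factors (KLFs) are zinc finger transcription factors, several of which change how far the axons of neurons grow. The arrays measured RNA in retinal ganglion cells, the neurons whose axons form the optic nerve, purified from rats at postnatal day 4 and transduced with lentivirus carrying KLF7, KLF9, KLF11, KLF16 or the red fluorescent protein mCherry. The study is understood to compare KLF9 and KLF16, studied as suppressors of axon growth, with KLF7 and KLF11, studied as promoters, and to have followed up the phosphatase gene Dusp14. There were 5 arrays with KLF7, 6 with KLF9, 6 with KLF11, 6 with KLF16 and 5 with mCherry, the control in each comparison. Values are log2 intensity per probe set, and arrays within a table correlated at 0.981 to 0.997 for KLF7, 0.964 to 0.998 for KLF9, 0.985 to 0.999 for KLF11 and 0.981 to 0.998 for KLF16. The number of arrays limits the precision of every value below.

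The transduced genes were read first. Klf9 averaged 11.39 ± 0.10 (SD, n = 6) on KLF9 arrays and 12.08 ± 0.07 (n = 5) on mCherry arrays, a log2 change of -0.69 (exact permutation p = 0.00216). Klf11 averaged 8.13 ± 0.42 (n = 6) on KLF11 arrays against 9.22 ± 0.24 (n = 5), a change of -1.10 (exact permutation p = 0.00216). Klf16 stood at 5.00 ± 0.08 (n = 6) on KLF16 arrays against 5.40 ± 0.30 (n = 5), a change of -0.40 (exact permutation p = 0.00216), with an adjusted p of 0.0351 that rose to 0.0774 with the replicate block. That adjusted p was also 0.0753, 0.0655, 0.0628 and 0.0608 without KLF16 array 1, 2, 3 or 4, and 0.0594 and 0.0698 without mCherry array 1 or 5. On the brightest Klf7 probe set no difference passed the test, at 11.87 ± 0.13 (n = 5) against 11.95 ± 0.23 (n = 5, exact permutation p = 0.492). A second Klf7 probe set read 12.71 ± 0.74 (n = 5) on KLF7 arrays and 10.68 ± 0.57 (n = 5) on mCherry arrays, a change of 2.03 (exact permutation p = 0.00794). With KLF9, KLF11 and KLF16 that probe set differed from mCherry by 0.20, -0.31 and -0.57, and none of these passed the test, so its values go with the KLF7 label. The other 2 Klf7 probe sets differed by -0.10 and 0.43 on KLF7 arrays, and neither passed. In the deposited alignments, whose genome build is not given in the sources used here, the brightest probe sets lie on chromosome 9 from 62690709 to 62691439 for Klf7, chromosome 1 from 226420948 to 226446456 for Klf9, chromosome 6 from 42306970 to 42307931 for Klf11 and chromosome 7 from 10658161 to 10658697 for Klf16. The constructs held open reading frames, and whether these probe sets lie inside them could not be read from the sources used here. Lower values were not limited to the own group. In limma without the block, Klf11 changed by -2.61 with KLF9 (adjusted p = 4.61e-05) and -0.87 with KLF16 (0.0398). Klf16 changed by -0.46 with KLF9 (0.00592) and 2.11 with KLF7, and Klf9 by -0.19 with KLF16 (0.0435). Klf11 and Klf9 with KLF7 (0.09 and 0.05) and Klf16 and Klf9 with KLF11 (-0.25 and -0.27) did not pass. Block values are not given for these. Why Klf9, Klf11 and Klf16 were lower in their own groups is left open, and each group is named as its arrays were labelled.

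KLF9 changed the most genes against mCherry, 6297 of 14217 (3546 higher, 2751 lower). KLF16 changed 2973 (1822 higher, 1151 lower), KLF7 2030 (1234 higher, 796 lower) and KLF11 461 (148 higher, 313 lower). With the replicate block the counts were 6628 for KLF9, 3146 for KLF16, 2546 for KLF7 and 437 for KLF11. The genes called in the same direction in both fits numbered 6046, 2501, 1876 and 311. Similar totals therefore hide a turnover of genes, which is largest in proportion for KLF11. The share of higher genes depends on scaling for KLF16 and KLF7. For KLF16 it was 61.3% as deposited, 53.8% after quantile normalisation and 45.6% after median centring, and for KLF7 60.8%, 52.8% and 52.2%. In the authors' deposited table, their own adjusted p-values under 0.05 number 8729 probe sets for KLF9, 2829 for KLF16, 1679 for KLF7 and 242 for KLF11. The KLF11 count fell to 293, 297 and 294 without KLF11 array 2, 3 or 4, and to 304 without mCherry array 5.

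**Figure D1:**
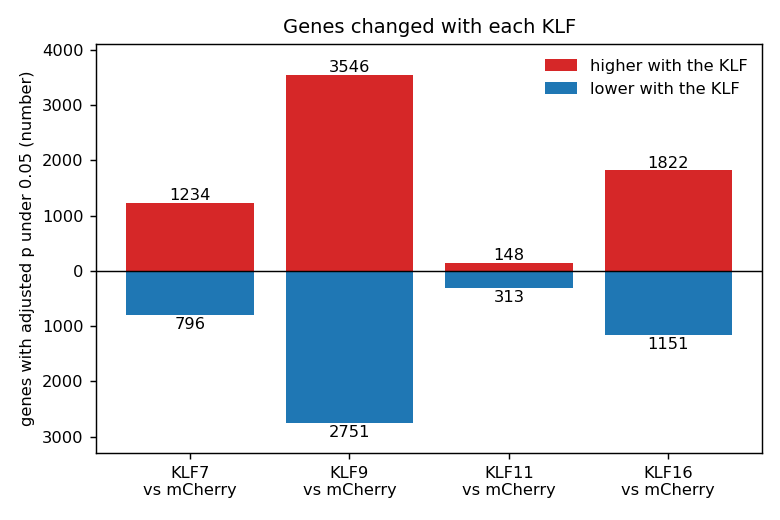
Number of genes past an adjusted p of 0.05 in each comparison with mCherry, drawn upwards for genes higher and downwards for genes lower with the KLF. KLF9 has the longest bars, 3546 and 2751, and KLF11 the shortest, 148 and 313.

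Dusp14 encodes a dual-specificity phosphatase that acts on MAP kinases. It rose 3.23-fold with KLF9, from 8.88 ± 0.17 (SD, n = 5) to 10.57 ± 0.17 (n = 6), and 2.08-fold with KLF16, from 8.76 ± 0.15 (n = 5) to 9.82 ± 0.23 (n = 6), each with an exact permutation p of 0.00216. With KLF7 it fell to 0.588-fold, from 8.61 ± 0.17 (n = 5) to 7.84 ± 0.23 (n = 5, exact permutation p = 0.00794). With KLF11 it was 8.71 ± 0.17 (n = 6) against 8.71 ± 0.13 (n = 5), with an exact permutation p of 0.944 and no settled sign. In limma, its log2 changes were 1.69 ± 0.10 (SE) for KLF9 (adjusted p = 2.17e-07), 1.06 ± 0.12 for KLF16 (0.000339), -0.77 ± 0.12 for KLF7 (0.00281) and 0.01 ± 0.09 for KLF11 (0.98). The probe set aligns to chromosome 10, minus strand, from 72335934 to 72336408, in a build not given in the sources used here. It has 2 deposited alignments, the other on an unplaced sequence.

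**Figure D2:**
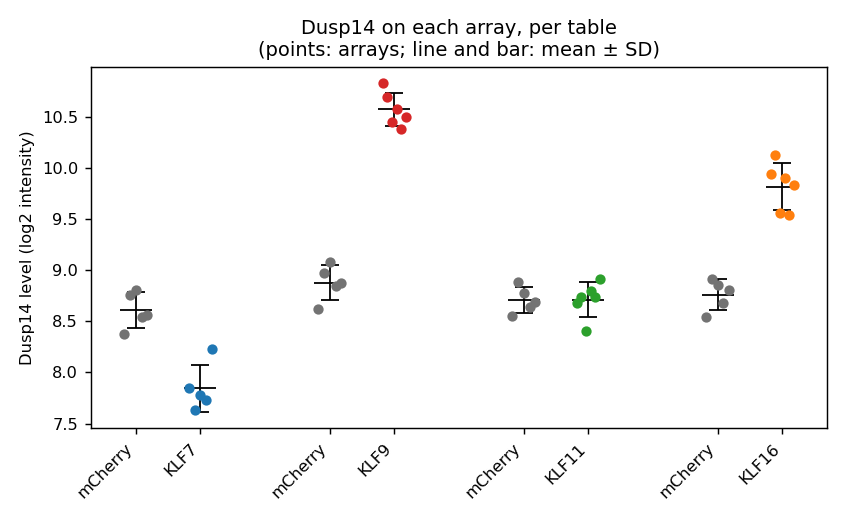
Dusp14 level in log2 intensity on each array, grouped by table, with the mCherry arrays of that table in grey beside the KLF arrays; points are arrays, and lines and bars are the mean and SD. KLF9 arrays average 10.57 and KLF16 arrays 9.82, above all mCherry arrays of their tables, and KLF7 arrays average 7.84, below theirs.

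With KLF7, the p53 effector gene Perp rose from 2.90 to 8.30 log2 units (log2 change 5.40 ± 0.15 SE, n = 5 and 5, limma adjusted p = 1.47e-07). The calcium-binding protein gene S100a6 rose by 5.28 ± 0.73, the mitochondrial translocator gene Tspo by 4.01 ± 0.53, the protease-like gene Prss35 by 3.83 ± 0.27 and the argininosuccinate synthase gene Ass1 by 3.77 ± 0.37 (adjusted p from 3.48e-05 to 0.00134). The largest falls included another family member, Klf2, at -2.88 ± 0.38, the collagen gene Col25a1 at -2.47 ± 0.37, Tmem178a at -2.23 ± 0.44, B3galt5 at -2.02 ± 0.26 and Ppargc1a, a coactivator of mitochondrial biogenesis, at -2.0 ± 0.24 (adjusted p from 0.000694 to 0.0088). Of 18 KLF and SP transcription factors 4 rose and 2 fell, with Klf16 up by 2.11 ± 0.15 and Klf10 by 2.04 ± 0.15.

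Of 38 synaptic genes 13 fell with KLF7 and 2 rose. The glutamate receptor subunits Gria3, Gria1 and Gria2 changed by -1.79 ± 0.38, -1.34 ± 0.22 and -1.33 ± 0.13, while the vesicle fusion gene Stx1a rose by 1.36 ± 0.16 (camera adjusted p = 0.00254). Of 37 axon guidance genes 12 fell, among them Sema5a at -1.71 ± 0.26 and the semaphorin receptor Nrp2 at -1.18 ± 0.16, and 3 rose (camera adjusted p = 0.0208). Cholesterol synthesis genes rose in 7 of 20 cases and fell in 0, with Ebp at 0.73 ± 0.14, Mvk at 0.60 ± 0.13 and Lss at 0.50 ± 0.12 (camera adjusted p = 8.79e-05). These 3 list calls were lost with an estimated correlation (adjusted p = 0.381 with an estimated correlation for each). The axon guidance call was also lost with the replicate block (0.0758) and without mCherry array 1 or 2 (0.0564 and 0.0563), and the synaptic call without mCherry array 2 (0.0561). Gria3 stood at -1.66 without the arrays numbered 1 (adjusted p = 0.0551).

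Without the block, none of the lists below passed camera with KLF7. Among retinal ganglion cell markers 5 of 18 rose, such as the surface glycoprotein gene Thy1 at 0.90 ± 0.08, Rbpms2 at 0.87 ± 0.07 and the neurofilament gene Nefh at 0.76 ± 0.12, and 5 fell, such as Nrn1 at -0.72 ± 0.10. Among 32 regeneration-associated genes 6 rose and 7 fell, with the small heat shock protein gene Hspb1 at 1.92 ± 0.37, Lgals1 at 1.38 ± 0.19 and the neuropeptide gene Vip at -1.91 ± 0.35. Neurite growth and growth cone genes rose in 3 of 27 cases, including the tubulin gene Tubb3 at 0.52 ± 0.09 and Dpysl5 at 0.50 ± 0.10, and fell in 0 (6 rose and 1 fell with the replicate block). Voltage-gated channels fell in 7 of 34 cases, with the sodium channel gene Scn1a at -1.49 ± 0.30 and Kcnip4 at -0.95 ± 0.12, and rose in 4. Immediate early genes rose in 4 of 19 cases (Junb 1.26 ± 0.23) and fell in 1, Fos, at -0.96 ± 0.17. Apoptosis regulators went both ways in 5 of 20 cases, with Hrk at -1.25 ± 0.18, Bcl2l11 at -1.08 ± 0.08 and Bid at 0.98 ± 0.11. Of 35 cell cycle genes E2f1 rose by 1.25 ± 0.16 and Mcm7 fell by 0.97 ± 0.16. Hormone-response genes fell in 7 of 19 cases, such as the thyroid hormone receptor gene Thrb at -1.06 ± 0.16, and rose in 2 (camera adjusted p = 0.0565, and 0.0372 with the replicate block, adjusted p = 0.566 with an estimated correlation). Of 20 clock genes Bhlhe40 rose by 2.49 ± 0.43 and 4 fell. Of 14 p53 targets 2 rose, Cdkn1a by 1.10 ± 0.13, and 1 fell, and among 17 TGF-beta targets 3 rose, Id1 by 2.20 ± 0.38, and 2 fell.

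In the remaining KLF7 lists, members higher and lower numbered 3 and 2 of 18 phosphatases and ERK inhibitors, 3 and 1 of 28 integrated stress response genes, 4 and 0 of 20 glycolysis genes, 1 and 2 of 50 oxidative phosphorylation genes, 2 and 1 of 21 astrocyte and Müller glia markers, and 0 and 2 of 18 amacrine and horizontal cell markers, Pax6 at -0.72 ± 0.08 among the latter. In limma, 0 members changed among 24 ribosomal proteins, 19 microglia markers, 22 photoreceptor and bipolar markers, 26 endothelial, pericyte and fibroblast markers and 14 oligodendrocyte lineage markers, with 0, 0, 2, 1 and 0 members at an unadjusted p under 0.05. Interferon response genes rose in 1 of 34 cases, Irf9, at 0.93 ± 0.22. With the replicate block 8 rose and the camera adjusted p was 2.13e-05, against 0.0619 without it, and adjusted p = 0.796 with an estimated correlation and the block. On KLF7 array 1 this list stood 3.51 above the other KLF7 arrays, and microglia markers 4.10 above. Of 678 members over all lists 68 were higher and 73 lower, beside 1234 and 796 of all 14217 genes. Adjusted over the list alone these members numbered 76 and 81.

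With KLF9, the ciliary gene Cfap77 rose by 6.03 ± 0.17 (SE, n = 6 and 5, limma adjusted p = 3.81e-09), the tetraspanin gene Tspan33 by 5.21 ± 0.24 and Pdk2, a kinase that inhibits pyruvate dehydrogenase, by 5.00 ± 0.43. Interferon-induced genes stood beside them, with Oas1a at 5.27 ± 0.85, Ifi35 at 5.09 ± 0.39, Usp18 at 4.92 ± 1.08 and Oas1b at 4.49 ± 0.78 (adjusted p from 1.45e-06 to 0.00311). The largest falls were in the proteoglycan gene Cspg5 at -5.82 ± 0.20, the RNA-binding protein gene Rbm11 at -5.77 ± 0.17, the vesicle trafficking gene Rab3d at -5.66 ± 0.54, Igdcc4 at -5.65 ± 0.17 and Unc119 at -5.43 ± 0.35 (adjusted p from 3.81e-09 to 7.03e-06). KLF and SP factors went both ways, 6 up and 6 down of 18, with Klf13 at -4.42 ± 0.20, Klf11 at -2.61 ± 0.32 and Klf15 at 2.83 ± 0.23. Klf9 itself is among these falls.

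Genes of neurite growth and the growth cone cytoskeleton fell with KLF9 in 19 of 27 cases and rose in 0 (camera adjusted p = 2.54e-06). The microtubule protein gene Mapt changed by -1.68 ± 0.13, Dpysl3 by -1.42 ± 0.33, Dpysl5 by -1.31 ± 0.08 and Tubb3 by -1.12 ± 0.11. Oxidative phosphorylation genes rose in 37 of 50 cases and fell in 0 (camera adjusted p = 7.63e-08), by smaller amounts, such as Ndufv1 of complex I at 0.78 ± 0.10, Sdha of complex II at 0.69 ± 0.06 and Uqcrh of complex III at 0.66 ± 0.06. Cell cycle genes rose in 17 of 35 cases and fell in 0 (camera adjusted p = 0.000833), with the mitotic kinase gene Cdk1 at 2.86 ± 0.12 and the replication licensing genes Mcm7 at 2.10 ± 0.13 and Mcm2 at 2.00 ± 0.10. These 3 calls were lost with an estimated correlation (adjusted p = 0.326, 0.856 and 0.109 with an estimated correlation).

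Interferon response genes rose with KLF9 in 11 of 34 cases and fell in 0 (camera adjusted p = 0.0105, adjusted p = 0.856 with an estimated correlation). With the replicate block 22 rose (3.05e-05), and without the arrays numbered 1 19 rose. The camera call was lost without KLF9 array 1 (0.0576), without the dimmest 40% of genes (0.179) and in fry (0.0758, and 0.00424 with the replicate block). On the arrays numbered 1 the same list stood above the other arrays of its group by a median of 1.67 for mCherry and 2.00 for KLF9, and microglia markers by 3.62 and 3.28. Of 19 microglia markers 1 rose with KLF9, Cd14, at 3.12 ± 1.08 (adjusted p = 0.0364), and 0 fell. That call was lost without KLF9 array 1, 2, 3, 4 or 6 (adjusted p = 0.0658, 0.0622, 0.0529, 0.0527 and 0.0506) and without mCherry array 2, 4, 5 or 6 (0.0811, 0.0826, 0.0834 and 0.0849).

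Cholesterol synthesis genes fell in 12 of 20 cases and rose in 3, with the squalene synthase gene Fdft1 at -2.48 ± 0.25, Cyp51 at -1.72 ± 0.10 and Srebf2, a transcription factor of this pathway, at -1.64 ± 0.19. The list had a camera adjusted p of 0.0708, and 0.0436 with the replicate block (adjusted p = 0.708 with an estimated correlation). Apoptosis regulators fell in 6 of 20 cases, among them the pro-apoptotic genes Bid at -4.27 ± 0.28, Bok at -2.33 ± 0.26 and Casp9 at -2.07 ± 0.28, and rose in 4. Integrated stress response genes fell in 10 of 28 cases and rose in 3. Of 14 p53 targets 4 rose and 3 fell, including the cell cycle inhibitor gene Cdkn1a at -2.20 ± 0.12 and Bbc3 at -1.43 ± 0.13.

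Among 18 phosphatases and ERK feedback inhibitors 7 rose with KLF9, such as Dusp5 at 1.2 ± 0.07, and 2 fell. Immediate early genes rose in 9 of 19 cases, with Fosb at 3.20 ± 0.32 and Egr4 at 2.42 ± 0.33, and fell in 2. Synaptic genes rose in 11 of 38 cases and fell in 6, with Stx1a at -2.15 ± 0.18, Rab3c at 1.47 ± 0.09 and Vamp1 at 1.45 ± 0.06. Regeneration-associated genes rose in 10 of 32 cases and fell in 7, among the latter Myc at -2.31 ± 0.21, Hspb1 at -1.73 ± 0.24 and Lgals1 at -1.52 ± 0.25. Retinal ganglion cell markers rose in 6 of 18 cases and fell in 5, such as Jam2 at -1.07 ± 0.31 and Rbpms2 at -0.95 ± 0.09, with a median of 0.11 but a mean of -0.04. Axon guidance genes rose in 9 of 37 cases and fell in 8, with the ephrin receptor gene Epha3 at 1.69 ± 0.19 and the ligand gene Efnb3 at -1.63 ± 0.14. Glycolysis genes rose in 9 of 20 cases, Pfkp by 1.06 ± 0.11, and fell in 1, and ribosomal protein genes rose in 6 of 24 cases, Rplp0 by 0.46 ± 0.07, and fell in 0.

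Of the other KLF9 lists, channels had 6 of 34 higher and 11 lower, TGF-beta targets 6 of 17 higher (Id2 1.82 ± 0.16) and 1 lower, hormone-response genes 3 of 19 higher and 4 lower, and clock genes 3 of 20 higher (Cry1 1.95 ± 0.09) and 6 lower. The clock list had a median of -0.14 and a mean of 0.07. Markers of other cells moved in few cases: 3 higher and 1 lower of 21 astrocyte and Müller glia markers (Car2 1.55 ± 0.18), 3 higher and 2 lower of 18 amacrine and horizontal markers (Gad1 2.17 ± 0.28, Prox1 1.73 ± 0.16), 1 and 1 of 22 photoreceptor and bipolar markers, 0 and 1 of 26 endothelial, pericyte and fibroblast markers, and 0 and 3 of 14 oligodendrocyte lineage markers. Of 678 members over all lists 180 were higher and 125 lower, beside 3546 and 2751 of all 14217 genes. Adjusted over the list alone these members numbered 180 and 124. With KLF9 44.3% of all genes changed, so a list count near that share shows no effect particular to the list.

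**Figure D3:**
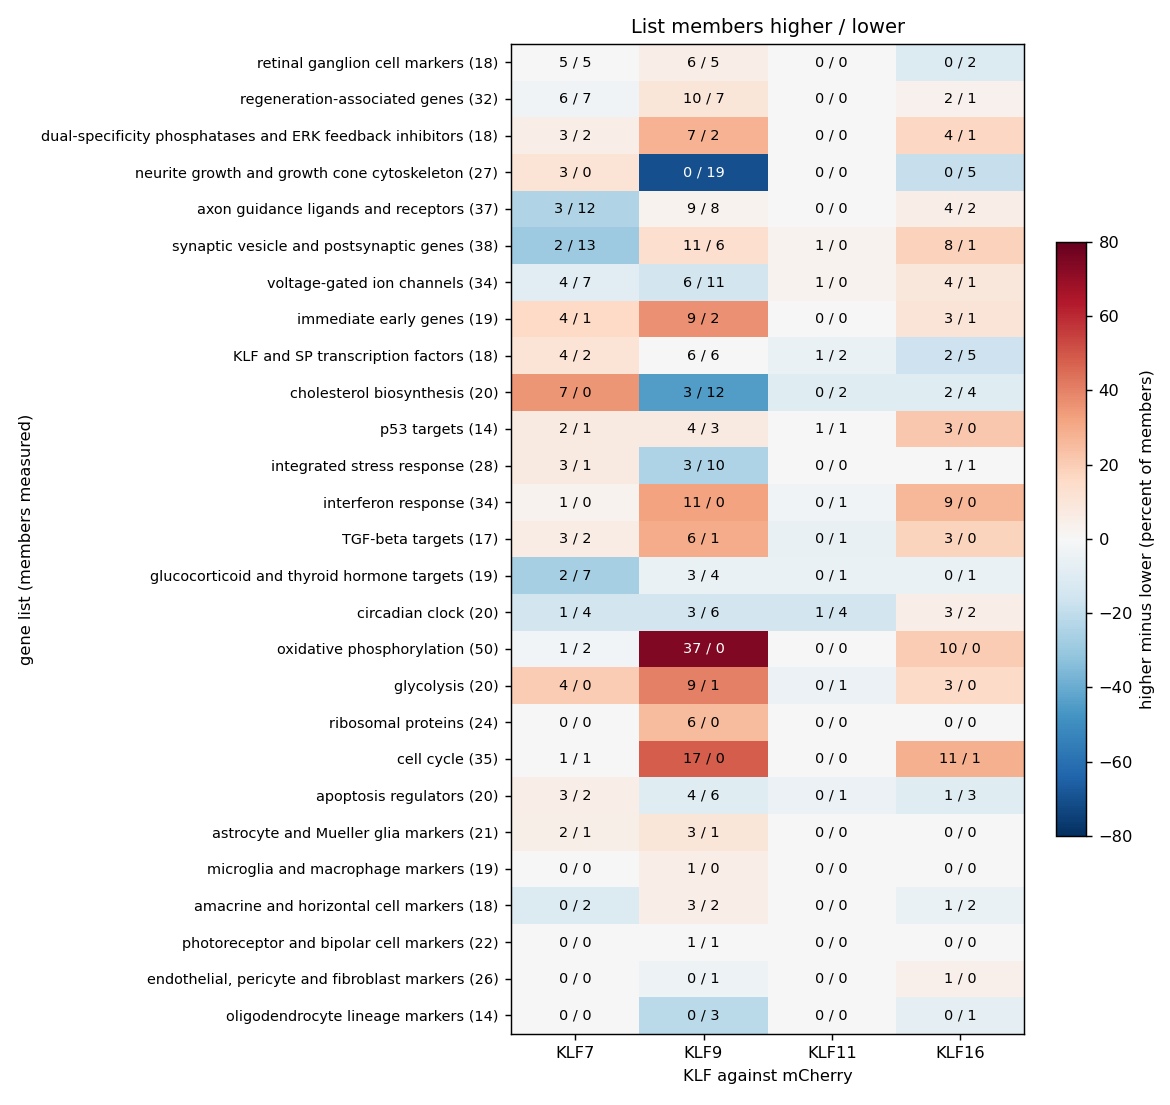
Members of each gene list reported that were higher / lower past an adjusted p of 0.05 with each KLF against mCherry; colour is higher minus lower in percent of the members measured, whose number follows the list name. The deepest colours are those of KLF9 for oxidative phosphorylation (37 / 0) and for neurite growth and growth cone cytoskeleton (0 / 19).

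With KLF11, most of the larger changes were falls. The kynurenine aminotransferase gene Kyat3 fell by 4.13 ± 0.17 (SE, n = 6 and 5, limma adjusted p = 1.32e-06), and Mpv17l, a mitochondrial and peroxisomal membrane protein gene, by 4.05 ± 0.20 (6.1e-06). Others were Klf10 at -3.05 ± 0.44, Mcrip2 at -2.93 ± 0.25, and genes of mitochondrial amino acid breakdown, Ivd at -2.88 ± 0.25, Aldh6a1 at -2.79 ± 0.40 and Dhtkd1 at -2.73 ± 0.20, with the kinase gene Rps6ka2 at -2.67 ± 0.20 (adjusted p from 0.0001 to 0.00383). Among the rises, Racgap1, a regulator of cytokinesis, changed by 2.02 ± 0.31 (adjusted p = 0.00571). The nicotinic receptor gene Chrna5 changed by 1.48 ± 0.30 (0.0238), a call lost with the replicate block (0.0525), without KLF11 array 1, 2 or 3 (0.0528, 0.0574 and 0.0542) and without mCherry array 4 or 6 (0.0529 and 0.0559).

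Few list members changed with KLF11. Of 18 KLF and SP factors Klf5 rose by 0.64 ± 0.11 and 2 fell (camera adjusted p = 0.0509, and 0.0485 with the replicate block, adjusted p = 0.716 with an estimated correlation). Klf11 itself is among these falls and part of that test. Of 20 clock genes 4 fell, including Bmal1 at -1.05 ± 0.17 and Per1 at -0.64 ± 0.11, and 1 rose. With the replicate block 2 clock genes fell and 0 rose, and Bmal1 had an adjusted p of 0.0507. Cholesterol synthesis genes fell in 2 of 20 cases, Mvk at -1.21 ± 0.11 and Ebp at -1.19 ± 0.21, and rose in 0. Single members fell among interferon genes (Stat2 -1.14 ± 0.15) and glycolysis genes (Slc2a1, a glucose transporter, -1.59 ± 0.21). Higher and lower members numbered 1 and 0 of 38 synaptic genes, 1 and 0 of 34 channels, 1 and 1 of 14 p53 targets, 0 and 1 of 17 TGF-beta targets, 0 and 1 of 19 hormone-response genes and 0 and 1 of 20 apoptosis regulators. Of 678 members over all lists 5 were higher and 14 lower, beside 148 and 313 of all 14217 genes. Adjusted over the list alone these members numbered 17 and 24.

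In limma, 0 members of the lists that follow changed with KLF11. Members higher and lower at an unadjusted p under 0.05 numbered 0 and 3 of 18 retinal ganglion cell markers, 2 and 3 of 32 regeneration-associated genes, 3 and 0 of 18 phosphatases, 1 and 2 of 27 neurite growth genes, 5 and 1 of 37 axon guidance genes, 0 and 2 of 19 immediate early genes, 1 and 2 of 28 integrated stress response genes, 1 and 0 of 50 oxidative phosphorylation genes and 5 and 1 of 35 cell cycle genes. They numbered 0 and 0 of 21 astrocyte and Müller glia markers, 0 and 1 of 18 amacrine and horizontal markers, 0 and 0 of 22 photoreceptor and bipolar markers, 0 and 1 of 26 endothelial, pericyte and fibroblast markers and 1 and 1 of 14 oligodendrocyte lineage markers. Camera called microglia markers lower, with 0 of 19 members past the threshold (0 and 3 unadjusted) and a median change of -0.88, and ribosomal proteins higher, with 0 of 24 members (2 and 0 unadjusted) and a median of 0.09. Each had a camera adjusted p of 0.00772, adjusted p = 0.894 with an estimated correlation, 0.322 without the dimmest 40% of genes and a fry adjusted p of 0.514. The microglia call was lost without mCherry array 1 (0.377), where microglia markers stood 3.62 above the other mCherry arrays against 0.84 on KLF11 array 1. It held without all arrays numbered 1 (0.000749, with a median of -0.11) and with the replicate block (4.29e-05, adjusted p = 0.716 with an estimated correlation). In pairs of arrays with the same number the microglia list was higher in 0 of 5, with differences from -2.24 to -0.31. The ribosomal call was lost without mCherry array 1 or 6 (0.2 and 0.0615) and without all arrays numbered 1 (0.085). With the replicate block, camera also called the endothelial, pericyte and fibroblast list (0.00292, adjusted p = 0.44 with an estimated correlation).

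With KLF16, interferon-induced genes and the serotonin receptor gene Htr2c led the rises. The chemokine gene Cxcl10 rose by 4.18 ± 0.92 (SE, n = 6 and 5, limma adjusted p = 0.00906), Usp18 by 4.14 ± 1.02 (0.0159), Oas1a by 3.48 ± 0.99 (0.0307) and Htr2c by 3.47 ± 0.28 (0.000162). The largest falls were in Cspg5 at -2.56 ± 0.27, the membrane trafficking gene Pacsin3 at -2.40 ± 0.37, Rbm11 at -2.16 ± 0.40, Kndc1 at -1.95 ± 0.34 and Bid at -1.91 ± 0.23. Klf13 fell by 1.69 ± 0.17 and Klf15 rose by 1.38 ± 0.26, among 5 falls and 2 rises in 18 KLF and SP factors. Klf16 itself is among these falls. The Oas1a call was lost without KLF16 array 2 or 3 (adjusted p = 0.0644 and 0.0646) and without mCherry array 2, 4, 5 or 6 (0.069, 0.0637, 0.0741 and 0.0631).

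Interferon response genes rose with KLF16 in 9 of 34 cases and fell in 0 (camera adjusted p = 0.000231, adjusted p = 0.698 with an estimated correlation, fry adjusted p = 0.119, and 0.00205 with the replicate block). With that block 20 rose, and without the arrays numbered 1 18 rose. On KLF16 array 1 this list stood 2.17 above the other KLF16 arrays, and microglia markers 3.45 above, while 0 of 19 microglia markers changed with KLF16 in limma (0 at an unadjusted p under 0.05). Cell cycle genes rose in 11 of 35 cases, with Mcm7 at 1.60 ± 0.15 and Cdk1 at 1.53 ± 0.14, and fell in 1 (camera adjusted p = 0.00032, adjusted p = 0.645 with an estimated correlation). Oxidative phosphorylation genes rose in 10 of 50 cases and fell in 0 (camera adjusted p = 0.000231, adjusted p = 0.698 with an estimated correlation, 0.0541 without the dimmest 40% of genes, fry adjusted p = 0.0945). Ndufv1 among them changed by 0.44 ± 0.11 (adjusted p = 0.0169, and 0.0693 with the replicate block). Neurite growth and growth cone genes fell in 5 of 27 cases, with the actin regulator Enah at -0.56 ± 0.12 and Marcksl1 at -0.37 ± 0.08, and rose in 0 (camera adjusted p = 0.00706, adjusted p = 0.698 with an estimated correlation).

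**Figure D4:**
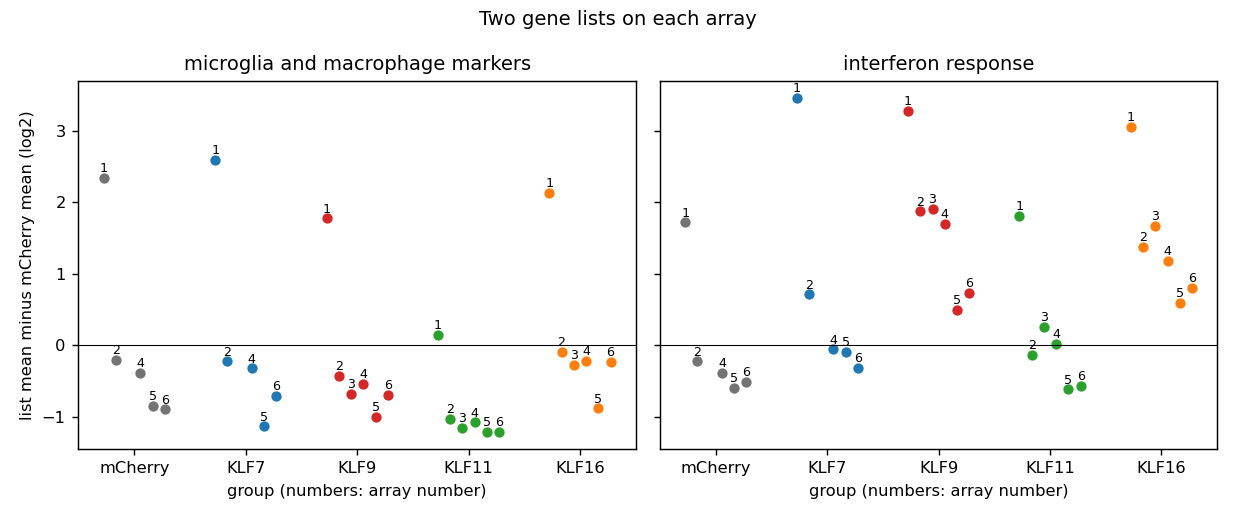
Mean of the microglia marker list and of the interferon response list on each array, as log2 difference from the mCherry mean of the same table; each point is an array with its number, and columns are groups. Arrays numbered 1 stand apart in microglia markers, by a median of 3.62 log2 units for mCherry and 0.84 for KLF11 against the other arrays of their group.

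Members of other lists moved with KLF16 as follows. Synaptic genes rose in 8 of 38 cases, Vamp1 by 0.68 ± 0.10, and fell in 1. Axon guidance genes rose in 4 of 37 cases, including the ephrin receptor genes Epha3 at 1.61 ± 0.39 and Epha4 at 1.32 ± 0.18, and fell in 2. Epha3 was 1.57 without the arrays numbered 1 (adjusted p = 0.0513). Of 18 phosphatases 4 rose and 1 fell. Cholesterol synthesis genes went both ways, 2 up and 4 down of 20, with Ebp at 0.96 ± 0.19, Stard4 at 0.85 ± 0.13, Tm7sf2 at -0.79 ± 0.17 and Cyp51 at -0.78 ± 0.10. Of 18 retinal ganglion cell markers Jam2 fell by 0.53 ± 0.12 and Nefm by 0.46 ± 0.12, and 0 rose. Regeneration-associated genes rose in 2 of 32 cases and fell in 1, Myc, at -0.77 ± 0.19. Channels rose in 4 of 34 cases, such as the calcium channel subunit gene Cacna2d3 at 0.73 ± 0.13, and fell in 1.

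Higher and lower members with KLF16 numbered 3 and 1 of 19 immediate early genes, 3 and 0 of 14 p53 targets, 1 and 1 of 28 integrated stress response genes, 3 and 0 of 17 TGF-beta targets (Id2 1.04 ± 0.17), 0 and 1 of 19 hormone-response genes, 3 and 2 of 20 clock genes, 3 and 0 of 20 glycolysis genes (Pfkp 0.65 ± 0.10) and 1 and 3 of 20 apoptosis regulators. Among cell type markers they were 1 and 2 of 18 amacrine and horizontal markers (Prox1 1.02 ± 0.13), 1 and 0 of 26 endothelial, pericyte and fibroblast markers (Pdgfra 1.10 ± 0.24) and 0 and 1 of 14 oligodendrocyte lineage markers. In limma, 0 ribosomal protein, astrocyte and Müller glia, and photoreceptor and bipolar genes changed, with 1, 4 and 0 at an unadjusted p under 0.05. Of 678 members over all lists 75 were higher and 37 lower, beside 1822 and 1151 of all 14217 genes. Adjusted over the list alone these members numbered 79 and 34.

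With the replicate block, these further list counts moved by over 1.5-fold. Higher and lower members with KLF7 were then 5 and 13 for axon guidance, 4 and 2 for immediate early genes, 1 and 1 for p53 targets, 4 and 4 for the integrated stress response, 3 and 1 for TGF-beta targets, 1 and 7 for clock genes, 1 and 1 for oxidative phosphorylation, 1 and 3 for the cell cycle, 2 and 2 for astrocyte and Müller glia markers, 1 and 0 for microglia markers and 1 and 0 for endothelial, pericyte and fibroblast markers. With KLF9 they were 7 and 2 for TGF-beta targets, 9 and 2 for glycolysis, 6 and 1 for ribosomal proteins, 1 and 3 for microglia markers and 0 and 2 for endothelial, pericyte and fibroblast markers. With KLF11 they were 1 and 1 for regeneration-associated genes, 1 and 0 for neurite growth, 2 and 2 for KLF and SP factors, 1 and 0 for p53 targets, 0 and 1 for the integrated stress response, 1 and 1 for TGF-beta targets, 0 and 1 for the cell cycle, 1 and 0 for apoptosis regulators, 1 and 2 for astrocyte and Müller glia markers, 0 and 3 for microglia markers and 0 and 2 for endothelial, pericyte and fibroblast markers. The KLF16 counts became 5 and 1 for hormone-response genes, 6 and 1 for regeneration-associated genes, 6 and 0 for immediate early genes, 6 and 0 for TGF-beta targets, 5 and 4 for synaptic genes, 3 and 2 for KLF and SP factors, 3 and 2 for the integrated stress response, 5 and 2 for channels, 1 and 2 for retinal ganglion cell markers, 3 and 1 for glycolysis and 3 and 3 for apoptosis regulators. Among KLF16 cell type markers they became 1 and 0 for astrocytes and Müller glia, 1 and 0 for microglia, 3 and 1 for amacrine and horizontal cells, and 3 and 0 for endothelial cells, pericytes and fibroblasts.

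Comparing KLF9 and KLF16 with KLF7 and KLF11 sets the mean of the factors studied as growth suppressors against the mean of those studied as promoters. A large difference in 1 factor alone can produce a call, so a call does not mean that both suppressors differ from both promoters. The comparison called 7519 genes (4055 higher, 3464 lower with KLF9 and KLF16). Cfap77 was higher by 4.22 ± 0.23 (SE, limma adjusted p = 2.83e-14), Htr2c by 4.05 ± 0.13 and Tspan33 by 3.79 ± 0.11, while Cspg5 differed by -4.67 ± 0.15, Rbm11 by -4.23 ± 0.20 and the matrix protein gene Vwa1 by -4.01 ± 0.16. Neurite growth genes were lower in 21 of 27 cases and higher in 1 (camera adjusted p = 2.08e-05, adjusted p = 0.123 with an estimated correlation). Against mCherry, 19 of these 27 fell with KLF9, 5 with KLF16 and 0 with KLF11 or KLF7, and 3 rose with KLF7. Cholesterol synthesis genes were lower in 14 of 20 cases and higher in 4 (0.00809, adjusted p = 0.803 with an estimated correlation). Oxidative phosphorylation genes were higher in 37 of 50 cases and lower in 0 (5.19e-06, adjusted p = 0.803 with an estimated correlation), and cell cycle genes higher in 20 of 35 and lower in 1 (0.00161, adjusted p = 0.123 with an estimated correlation). These differences join tables that were normalised separately, and that part of the error is not in their p-values.

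KLF9, KLF11 and KLF16 form one subgroup of the family and KLF7 belongs to another. The mean of the subgroup differed from KLF7 in 6702 genes (3554 higher, 3148 lower). Here too a large difference in 1 member can produce a call. Klf2 was higher by 3.76 ± 0.29 (SE, limma adjusted p = 5.76e-11), the secreted Wnt modulator gene Sfrp2 by 3.59 ± 0.24 and Ppargc1a by 3.17 ± 0.13, and Perp differed by -5.33 ± 0.11, S100a6 by -4.79 ± 0.48 and Prss35 by -4.20 ± 0.14. Synaptic genes were higher in 18 of 38 cases and lower in 5 (camera adjusted p = 0.00496, adjusted p = 0.334 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 20 and higher in 2 (0.000449, adjusted p = 0.481 with an estimated correlation), and neurite growth genes lower in 16 of 27 and higher in 1 (0.000413, adjusted p = 0.27 with an estimated correlation). Oxidative phosphorylation genes were higher in 36 of 50 and lower in 1 (camera adjusted p = 5.77e-05, adjusted p = 0.708 with an estimated correlation). Against mCherry, 37 of these 50 rose with KLF9, 10 with KLF16 and 0 with KLF11. Cell cycle genes were higher in 17 of 35 and lower in 2 (camera adjusted p = 0.00403, adjusted p = 0.229 with an estimated correlation).

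Between single KLFs, 9099 genes differed in at least 1 of the 6 pairs. KLF9 against KLF7 differed in 7510 genes, with Cfap77 at 6.06 ± 0.33 (SE) and Cspg5 at -6.68 ± 0.22, and KLF9 against KLF11 in 6806, with Mpv17l at 6.18 ± 0.20 and Igdcc4 at -6.08 ± 0.22. KLF9 and KLF16 differed from each other in 4797 genes (2485 higher, 2312 lower with KLF9; 3354 and 1862 after median centring, 676 and 1247 with a 1.5-fold minimum), with Ifi35 at 3.73 ± 0.68, Cfap77 at 3.67 ± 0.32, the tubulin-binding protein gene Tppp3 at -4.73 ± 0.18 and the adhesion molecule gene Epcam at -4.19 ± 0.28. KLF16 against KLF7 gave 6057 genes, with Klf2 at 3.83 ± 0.35 and Perp at -5.31 ± 0.14, and KLF16 against KLF11 4336, with Mpv17l at 5.55 ± 0.20 and Cspg5 at -2.66 ± 0.21. KLF11 against KLF7 gave the fewest, 3855, with Klf2 at 3.70 ± 0.35 and Perp at -5.18 ± 0.14.

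Across genes, the log2 changes of KLF9 and KLF16 against mCherry correlated at r = 0.826 over 14217 genes, which are not independent replicates. Both rose in 1693 genes and both fell in 1040, where independent lists would share 454.4 and 222.7, and 27 genes changed in opposite directions against 639.6. Unchanged groups simulated against the same mCherry arrays correlated at a mean of 0.507. The covariance was 0.265 against 0.0183 simulated, and splitting the mCherry arrays between the comparisons left a mean r of 0.718. KLF9 and KLF7 correlated at -0.243 (simulated 0.468, split -0.277) with 1147 opposite genes against 437.3 for independent lists, and KLF16 and KLF7 at -0.163 (simulated 0.468, split -0.239) with 687 against 201.9. The pairs with KLF11 lay near 0 once the controls were split: KLF9 and KLF11 at 0.133 (split 0.0519), KLF16 and KLF11 at 0.193 (split 0.0452) and KLF11 and KLF7 at 0.121 (split -0.0302), with simulated means of 0.535, 0.523 and 0.516. These pairs had 152, 87 and 83 opposite genes against 106.7, 52.1 and 35.5 for independent lists. They shared 90, 68 and 36 rises against 36.9, 19.0 and 12.9, and 121, 79 and 53 falls against 60.6, 25.3 and 17.5. Covariances were -0.0764 and -0.0261 for the pairs of KLF7 with KLF9 and KLF16 (simulated 0.0173 and 0.0167), and 0.0290, 0.0215 and 0.0132 for the pairs with KLF11 (simulated 0.0184, 0.0180 and 0.0176). The simulated value leaves out real effects and the independent value leaves out the shared controls, so neither excess measures a shared effect.

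**Figure D5:**
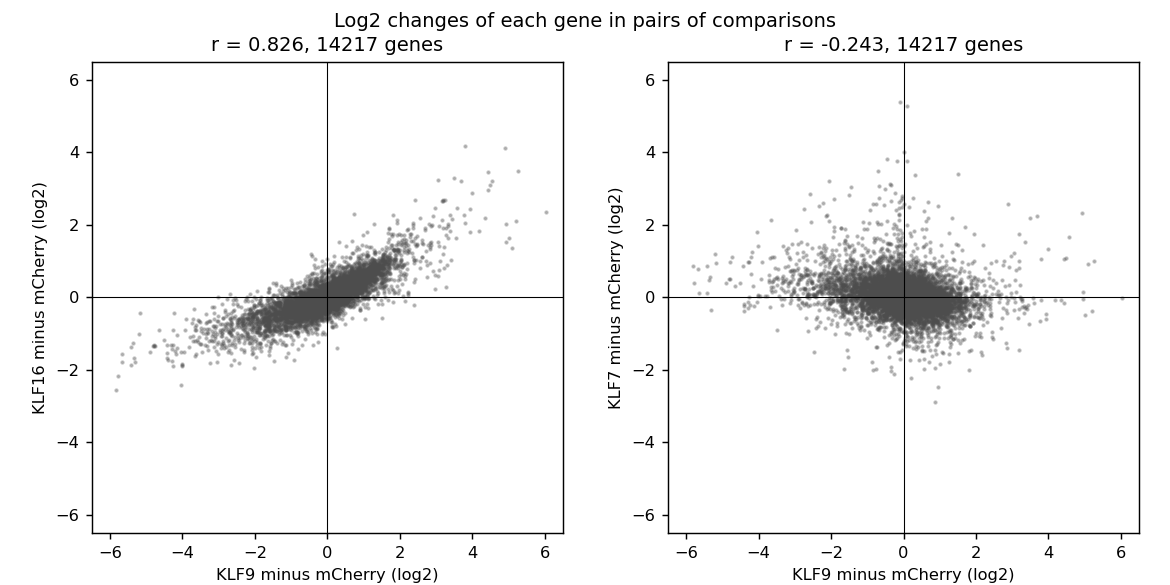
Log2 change of each of 14217 genes (points) against mCherry, KLF9 on the horizontal axes and KLF16 (left) or KLF7 (right) on the vertical axes. Points follow the rising diagonal for KLF9 and KLF16 (r = 0.826) and spread with a slight opposite slope for KLF9 and KLF7 (r = -0.243).

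In all 4 comparisons, 8 genes rose and 7 fell, where independent lists would share 0.411 and 0.275. Both directions together made 15, where unchanged groups simulated against these controls shared a mean of 7.78 and up to 675. Chrna5 rose by 2.51, 0.94, 1.48 and 1.43 with KLF7, KLF9, KLF11 and KLF16, and the membrane protein gene Tmem132e by 0.97, 1.61, 0.83 and 1.26. Nupr2 changed by -0.50, -1.14, -1.61 and -0.47, and the aldehyde dehydrogenase gene Aldh9a1 by -0.72, -1.99, -1.24 and -0.47. The count was 8 without KLF11 array 3 and 7 without mCherry array 4 or 6. With KLF11 the Tmem132e call was lost without KLF11 array 1, 2, 3 or 4 (adjusted p = 0.0552, 0.0672, 0.063 and 0.0653) and without mCherry array 2, 4 or 6 (0.0611, 0.0657 and 0.0594), and the Chrna5 call without KLF11 array 1, 2 or 3 (0.0528, 0.0574 and 0.0542) or mCherry array 4 or 6 (0.0529 and 0.0559). With KLF16 the Aldh9a1 call was lost without KLF16 array 1, 3 or 4 (0.0502, 0.0527 and 0.055) and without mCherry array 2, 4 or 6 (0.0674, 0.0682 and 0.0507). The replicate block also ended the Tmem132e call with KLF11 and the Aldh9a1 call with KLF16.

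Genes that rose with 1 KLF and fell with another numbered 1313 over the 6 pairs. The phospholipid-binding protein gene Anxa5 rose by 2.13 with KLF7 and fell by 3.66 with KLF9, and Coch rose by 2.86 and fell by 2.57. Mpv17l rose by 2.13 with KLF9 and by 1.5 with KLF16 and fell by 4.05 with KLF11, and Ivd rose by 2.05 and 1.06 and fell by 2.88. Pacsin3 rose by 1.82 with KLF7 and fell by 2.40 with KLF16, and the glycogen phosphorylase gene Pygl rose by 2.44 and fell by 1.5. Klf10 rose by 2.04 with KLF7 and fell by 3.05 with KLF11, and Tcf19 rose by 2.63 and fell by 1.49.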

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

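The tests of array-wide distortion, of interferon and microglia genes behind the correlation, and of other splits of the arrays were set before their results were seen. All other tests in this part were chosen after, among them the splits of comparisons between KLFs that keep the numbers apart and the use of simulated groups against the count of KLF11.

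The first pattern is the rise of interferon response genes with KLF9 and KLF16. In pairs of arrays with the same number the list was higher with KLF9 by a mean of 1.62 log2 units (95% interval 1.13 to 2.11). With KLF16 it was higher by 1.41 (1.24 to 1.57), and both were higher in 5 of 5 pairs. This argues against a batch shared by arrays of one number, which cancels in such pairs by design. A batch that goes with the group was not tested. Microglia markers differed in those pairs by -0.179 for KLF9 (upper bound 0.108, where 1.73 would be needed). For KLF16 they differed by 0.145 (upper bound 0.524, where 1.48 would be needed). These values argue against a larger amount of microglia as the source. A stronger interferon response in the microglia present need not change these markers, so the test cannot address it. The virus preparation cannot be told apart from the KLF, since each preparation goes with 1 group; of the other infected arrays KLF11 differed by 0.103 (-0.12 to 0.33), where microglia markers lower by 0.877 could hide a rise, and KLF7 by 0.743 (-0.04 to 1.52, higher in 5 of 5 pairs). A response to KLF9 and KLF16 themselves stays open as a hypothesis, beside one to their virus preparations.

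The second pattern is the high level of microglia markers on arrays numbered 1. They stood above the other arrays of their group by a median of 3.62 log2 units for mCherry, 4.10 for KLF7, 3.28 for KLF9, 0.84 for KLF11 and 3.45 for KLF16, with the lysozyme gene Lyz2 at 12.07 on mCherry array 1 against 7.77 ± 1.23 (SD, n = 4) and at 10.46 on KLF11 array 1 against 6.46 ± 0.53 (SD, n = 5). Of random lists of matched level, 0% reached these values in any group, which argues against a distortion of the whole array. On the arrays numbered 1, the ganglion cell list and the lists of other retinal cell types deviated by medians from only -0.0691 to 0.0937 over the groups. The interferon list deviated by 1.54 to 3.51. Carry-over of microglia through the purification could raise the microglia markers. Of these 19 markers 73.7% were highest on array 1 in at least 4 of the 5 groups. That is under the share set for the test, which was chosen after the pattern was seen, so carry-over stays open. No biological explanation was tested, as number 1 is not a group of the study.

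The third pattern is the correlation of log2 changes between KLF9 and KLF16 (r = 0.826). Splitting the mCherry arrays left at least 0.647, and the covariance was 0.265 against 0.0183 simulated, which argues against the shared controls as the whole source, although simulated unchanged groups reach r = 0.86. A response to any KLF virus is argued against by the correlations of KLF9 with KLF11 and KLF7, the higher of which was 0.133. Without 2643 genes of the interferon and microglia lists or following them over the mCherry arrays, r was 0.824 over 11574 genes. A shared response to KLF9 and KLF16 is a candidate explanation, found and tested on the same data.

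Single arrays far from the others of their group by Dixon's criterion were seen in 43 of 386 combinations of named gene and group. Chance gives about 1 in 20 groups, or 19.3. The same mCherry arrays enter once per table, so the combinations are not independent and 19.3 is only a guide. Of the 43, 20 were arrays numbered 1. Values are log2 levels, with the range of the other arrays in parentheses. In the KLF7 table, mCherry array 2 was high for Ass1 at 3.32 (2.09 to 2.44) and Stx1a at 9.76 (9.10 to 9.27), and mCherry array 1 was high for Irf9 at 9.06 (8.39 to 8.55) and E2f1 at 3.86 (3.28 to 3.42) and low for Pacsin3 at 6.67 (7.41 to 7.66). Also low were mCherry array 5 for Vip at 9.57 (10.72 to 11.08), mCherry array 6 for Rbpms2 at 9.99 (10.10 to 10.15) and KLF7 array 6 for Coch at 10.56 (11.03 to 11.13). KLF7 array 2 was high for Rbpms2 at 11.20 (10.89 to 10.94) and KLF7 array 6 for Bcl2l11 at 10.48 (10.13 to 10.21).

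In the KLF9 table, mCherry array 1 was high for Oas1a at 5.66 (2.28 to 2.76), Usp18 at 8.05 (3.05 to 3.29), Oas1b at 6.24 (2.84 to 3.20) and Cd14 at 8.21 (2.77 to 3.01), and low for Ndufv1 at 11.50 (11.91 to 12.04). KLF9 array 1 was high for Cd14 at 9.89 (5.59 to 7.07) and low for Mapt at 12.37 (12.81 to 13.07) and Chrna5 at 7.25 (7.76 to 8.02). KLF9 array 6 was high for Rbm11 at 3.57 (2.63 to 2.68), Igdcc4 at 3.42 (2.52 to 2.82) and Cyp51 at 10.83 (10.20 to 10.37), and low for Mcm7 at 10.03 (10.20 to 10.26). KLF9 array 4 was low for Vamp1 at 9.59 (9.84 to 9.94). mCherry array 2 was high for Dusp5 at 8.80 (8.52 to 8.59), Stx1a at 9.91 (9.07 to 9.27) and Epha3 at 3.02 (2.48 to 2.50), mCherry array 4 low for Fosb at 2.45 (3.63 to 3.91), and mCherry array 6 high for Egr4 at 4.57 (2.69 to 2.96) and low for Mpv17l at 6.87 (7.60 to 7.89).

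In the KLF11 table, KLF11 array 6 was high for Mpv17l at 3.67 (3.03 to 3.27), KLF11 array 1 low for Mcrip2 at 2.24 (3.29 to 3.88), mCherry array 1 high for Klf5 at 8.54 (8.01 to 8.11), mCherry array 4 low for Per1 at 8.25 (8.66 to 8.79) and mCherry array 5 low for Tcf19 at 6.52 (6.98 to 7.12). In the KLF16 table, mCherry array 1 was high for Cxcl10 at 7.0 (2.42 to 2.94), Usp18 at 7.97 (3.00 to 3.57), Oas1a at 5.42 (1.95 to 2.95) and Htr2c at 3.65 (2.48 to 2.63), and low for Ndufv1 at 11.39 (11.82 to 11.96). KLF16 array 1 was low for Klf16 at 4.85 (4.99 to 5.06) and Limk1 at 8.93 (9.26 to 9.39), mCherry array 4 low for Rbm11 at 8.73 (9.12 to 9.19) and mCherry array 2 high for Marcksl1 at 13.54 (13.25 to 13.32).

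Grouping by chance was tested with 100 splits of the arrays per comparison, of which 1, the real one, called as many genes in each. Whether the arrays of a group are separate cultures is not given, so these splits do not cover chance between cultures. For KLF9 and KLF16 against mCherry chance in the grouping of these arrays can be excluded. For KLF7 the free splits argue against it, but the splits that keep the numbers apart are too few to tell. For KLF11 it is left open, since in 3 of 20 simulations with its table, and in 1 of 20 with the replicate block, as many unchanged genes were called as changed in the data. Those simulations drew the groups independently, while KLF11 and mCherry arrays of the same number correlated at a mean of 0.374 in the data. They differ from the data in this, so they cannot settle the question. The real count and the highest other were 2030 and 1 for KLF7, 6297 and 4200 for KLF9, 461 and 0 for KLF11, and 2973 and 2299 for KLF16. Between KLFs they were 7519 and 4754 for KLF9 and KLF16 against KLF7 and KLF11, 6702 and 3915 for KLF9, KLF11 and KLF16 against KLF7, 7510 and 6730 for KLF9 against KLF7, 6806 and 4721 for KLF9 against KLF11, 4797 and 2874 for KLF9 against KLF16, 6057 and 3841 for KLF16 against KLF7, 4336 and 2178 for KLF16 against KLF11, and 3855 and 2681 for KLF11 against KLF7. The highest other splits with calls moved 1 to 5 arrays from the real one. Among the 32 splits that part the arrays of each number as the real one does, the real one alone called as many genes, with highest others of 3909 for KLF9, 0 for KLF11 and 0 for KLF16. For KLF7 there are 16 such splits, too few for a share under 0.05, with a real count of 2030 and a highest other of 0. Between KLFs, splits that exchange groups only among arrays of the same number also left 1, the real one, with as many genes. The highest others were 6293 over 100 splits for KLF9 and KLF16 against KLF7 and KLF11 and 3430 over 100 for KLF9, KLF11 and KLF16 against KLF7. Over 32 splits each they were 6612 for KLF9 against KLF7, 4620 for KLF9 against KLF11, 2136 for KLF9 against KLF16, 4786 for KLF16 against KLF7, 2210 for KLF16 against KLF11 and 2520 for KLF11 against KLF7. Between KLFs these splits argue against chance in the grouping of arrays. Each KLF has a table of its own, so they do not part the KLF from the normalisation of its table, and chance is not excluded. Simulations were run only for KLF9 against KLF16, where 0 of 20 called as many unchanged genes as changed in the data.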

How the results depend on the processing

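Joining all arrays in 1 fit and leaving out the arrays numbered 1 were chosen after the data were seen, as was their combination with the replicate block. Over all settings but left-out arrays, among the values that answer a comparison 211 kept their call and size, 42 moved, 8 lost the call and 5 reversed. Among named genes and list tests 2367 kept their call, 58 lost it and 2 changed sign. The replicate block lost 5 of 215 named genes, and quantile normalisation and median centring lost 0. Acadm, Hibadh and Hibch with KLF11, named further below, were not among the 215. Leaving out the arrays numbered 1 lost 3, or 12 with the block. These 12 were Ebp, Bmal1, Per1, Tmem132e and Aldh9a1 with KLF11, and Cntn2, Myc, Epha3, Tm7sf2, Nupr2, Aldh9a1 and Ivd with KLF16. Most named genes were picked for large changes, so these losses do not carry over to other genes. Leaving out the dimmest 40% of genes lost 0 of the 163 named genes that it kept. The dim named genes were not tested in that setting, and a measure of signal over background was not used here. Whether calls on dim genes hold is therefore not known. Using the series table as the source of values was not run, since it holds the same values on mixed scales. Where no cause is given below, the cause was not tested.

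A minimum of 1.5-fold left 982 genes for KLF7, 3671 for KLF9, 257 for KLF11 and 1341 for KLF16, and 3267 for KLF9 and KLF16 against KLF7 and KLF11, 3040 for KLF9, KLF11 and KLF16 against KLF7, 4744 for KLF9 against KLF7, 3708 for KLF9 against KLF11, 1923 for KLF9 against KLF16, 2952 for KLF16 against KLF7, 1623 for KLF16 against KLF11, 1500 for KLF11 against KLF7 and 5669 in at least 1 pair. An adjusted p under 0.01 left 955 for KLF7, 165 for KLF11 and 1486 for KLF16. Both are stricter by construction. Testing all probe sets, which counts more features, gave 12270 for KLF9 and KLF16 against KLF7 and KLF11, 10681 for KLF9, KLF11 and KLF16 against KLF7, 12286 for KLF9 against KLF7, 10735 for KLF9 against KLF11, 9496 for KLF16 against KLF7 and 15184 in at least 1 pair. Array weights gave 3980 genes for KLF7, 2153 for KLF11 (1113 higher, 1040 lower), 4891 for KLF16 and 2575 with opposite changes. KLF11 had 287 with the t-test, 997 with all arrays joined and 275 without the arrays numbered 1 and with the replicate block, where KLF16 had 1952.

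The count of 15 genes changed alike by all 4 KLFs was 7 with the t-test, 9 with trended and robust variance, 127 with array weights, 44 with all arrays joined and 6 without the arrays numbered 1 and with the block. Of the 14 list calls by camera, 0 held with an estimated correlation, and fry called 27. The fall of Klf16 on KLF16 arrays was lost with the replicate block (-0.40, adjusted p = 0.0774), the t-test (-0.40, 0.0585), trended and robust variance (-0.40, 0.0605), all probe sets (-0.40, 0.054), without the arrays numbered 1 (-0.37, 0.112) and without these and with the block (-0.36, 0.188). On other probe sets Klf7 differed by 2.03, -0.10 and 0.43, Klf9 by -0.53 and 0.0703, and Klf11 by 0.11 and -0.21. Dusp14 with KLF11 reversed to -0.0264 with quantile normalisation and to -0.0257 without the arrays numbered 1, both within its error of 0.09. Spearman's correlation was 0.213 for KLF9 and KLF11 and 0.793 for KLF9 and KLF16. With split mCherry arrays r was 0.0519 for KLF9 and KLF11, 0.718 for KLF9 and KLF16, 0.0452 for KLF16 and KLF11 and -0.0302 for KLF11 and KLF7, where fewer controls enter each comparison and none is shared.

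With each array left out in turn, 208 of 215 named genes held in every fit. Some genes whose call rested on a single array had already given way to others, so this share was partly fixed by the choice of genes. It does not measure how stable the calls of other genes are. The KLF11 count ranged from 293 to 472, the count for all 4 KLFs from 7 to 20, the change of Klf16 from -0.47 to -0.28 and that of Dusp14 with KLF11 from -0.035 to 0.0671. The correlation of KLF16 and KLF7 ranged from -0.195 to -0.0779, the latter without mCherry array 1. That of KLF11 and KLF7 ranged from 0.101 to 0.199, the latter without mCherry array 2.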

Other observations

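The branched-chain amino acid list and the Gene Ontology terms were chosen after results were seen, so all tests in this part are of that kind.

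Enzymes that break down the branched-chain amino acids leucine, isoleucine and valine in mitochondria fell together with KLF11. Of 28 such genes measured 14 fell and 2 rose (Auh 0.30 and Hibch 0.24). Besides Ivd and Aldh6a1, the subunit genes of the branched-chain ketoacid dehydrogenase changed by -2.36 ± 0.26 (SE) for Bckdhb, -1.99 ± 0.19 for Dbt and -0.65 ± 0.11 for Bckdha, those of methylcrotonyl-CoA carboxylase by -2.34 ± 0.17 for Mccc2 and -2.36 ± 0.23 for Mccc1, and Mmut, the methylmalonyl-CoA mutase gene, by -2.35 ± 0.33. Smaller falls were Pccb at -1.46 ± 0.26, Acat1 at -1.12 ± 0.13, Oxct1 at -1.10 ± 0.09, Hsd17b10 at -0.95 ± 0.12, Acadm at -0.56 ± 0.10 and Hibadh at -0.43 ± 0.08. The calls of Acadm, Hibadh and Hibch were lost with the replicate block (limma adjusted p = 0.069, 0.0561 and 0.0843). The list was written after 4 of its genes were seen among the falls. Without those 4, 10 of 24 fell where 0.528 would by chance (one-sided exact hypergeometric p = 3.46e-11), and camera gave p = 2.72e-08, or p = 0.0157 with an estimated correlation. Of these 24, 2 rose where 0.25 would by chance (exact hypergeometric p = 0.0256). With KLF9, 17 of the 28 rose and 6 fell, and 14 of the remaining 24 rose where 5.99 would by chance (exact hypergeometric p = 0.000504), while camera gave p = 0.047, or p = 0.0945 with an estimated correlation. In the other comparisons no excess among the 24 passed 0.05. With KLF7, 3 were lower and 4 higher where 1.34 and 2.08 would be by chance (exact hypergeometric p = 0.148 and 0.15), and with KLF16 4 were lower and 6 higher where 1.94 and 3.08 would be (exact hypergeometric p = 0.125 and 0.0774). A lower capacity for this breakdown with KLF11 is a hypothesis that RNA levels alone do not test.

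Gene Ontology terms, 963 with 10 to 300 genes over 8763 annotated genes, were tested for excess among the genes changed. With KLF9, 19 terms passed among the rises, led by translation (93 of 201 genes where 48.2 would by chance, adjusted p = 2.51e-09), rRNA processing (32 of 47, 8.83e-08), DNA replication (44 of 83, 3.21e-06) and ribosome biogenesis (21 of 28, 4.2e-06). With KLF16, 9 passed, among them rRNA processing (20 of 47, 0.000153), tRNA processing (18 of 41, 0.000181), ribosome biogenesis (13 of 28, 0.00243), DNA replication (23 of 83, 0.0152) and translation (42 of 201, 0.028). Small GTPase signalling led the falls with KLF9 (53 of 158, 0.0035; 3 terms passed) and was the 1 term among the falls with KLF16 (33 of 158, 7.75e-05). With KLF7, axon guidance (13 of 65, 0.0152) and long-term memory (6 of 16, 0.0383) passed among the falls. By the hypergeometric test 0 terms passed among the rises with KLF7 and among the rises or falls with KLF11, with 46, 7 and 23 terms at an unadjusted p under 0.05. Genes of a term are not independent, so these p-values are too small by an unknown amount.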
